A study of Mus musculus with 2 samples.

How the data were processed

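H3K4me3 was measured by chromatin immunoprecipitation sequencing in 2 biological replicates of lung from mouse embryos at embryonic day 16.5, both in the same group. The analysis started from 4 peak lists that the authors deposited, on the mm10 assembly per the labels. Each replicate had its own list, called from that replicate's filtered alignments per the deposited descriptions of the files. A pooled list was derived from both replicates' alignments, and a replicated list from the pooled list and both replicates' lists, per the same descriptions. The descriptions name a further source file for replicate 1's and the pooled list that is not named for replicate 2's list, and whether this makes the folds of the replicates ratios to different references is not given. The labels name an experiment that could serve as control, and its reads are not analysed here. The aligner, the peak caller, their versions and the exact reference of the fold are not given in the sources used here.

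Each deposited peak has a position, a score, a fold and p and q values. The score was scaled by the authors to at most 1000 and was not used. The fold is the authors' ratio of the peak's signal to background or control, as the peak caller gave it. The p-value and the q-value of each peak were deposited by the authors as −log10 values. The lowest −log10 p was 2.05 in replicate 1 and 2.00 in replicate 2, so the deposited lists reach down to a p of about 0.01, and 2.63% and 3.31% of their peaks had a q-value above 0.05. The summit is the authors' position of the peak's highest point. The peak lists give no read numbers, so the depth is unknown; the number of peaks limits the precision of a share of peaks, and the number of genes that of a share of genes. Wilson intervals (95%) cover counting error only. With 1 group of 2 replicates no test between groups of samples was possible, and values are given for both replicates.

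Gene models were those of GENCODE M21 on GRCm38, and the CpG content came from the GRCm38.p6 sequence, the same assembly as mm10. Chromosomes 1 to 19, X and Y were used, with 55413 genes, 132629 start sites and 21911 protein-coding genes. Peaks were called shared when the overlap covered at least 50% of either peak. The background was the same measure after moving all peaks along their chromosome by a random 1 to 10 Mb, 100 times. A gene was called marked in a list when a peak lay within 1000 bp of any of its transcripts' start sites. Its domain was the widest run of peaks no more than 1000 bp apart that reached this window, and its fold the highest of the peaks in the window. At 154 of the genes marked in both replicates (1.06%) the domains of the replicates did not overlap. A domain can belong to several genes, and 35.6% of marked genes had a start site of another gene within 1 kb, so that a peak there cannot be given to one of them. The CpG ratio was the observed over expected number of CpG in 1000 bp centred on the most upstream start site, and genes were split into 10 groups of equal size by it. A gene's domain and fold can come from another of its start sites, so the ratio need not be that of the promoter measured.

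The 20 gene lists and 5 families defined by their symbols were fixed before the data were examined, as were the tests and the alternatives, except where the text says otherwise; 4 list symbols had no protein-coding gene of that name in the annotation. The share of a list's genes marked in both replicates was compared with all other protein-coding genes by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the 25 lists and families, and again within these CpG groups by an exact conditional test. The median domain width of lists with at least 5 marked genes was compared with 100000 random sets of marked genes of the same size, and with sets matched on the CpG groups, by a 2-sided permutation test. These tests run over genes, which are not independent replicates of the tissue. Genes were named by a rule fixed in advance: the 15 widest domains, up to 4 widest and 4 unmarked members of each list, all Hox genes, members marked in 1 replicate only, the 5 highest genes marked in only 1 replicate, and the 10 widest domains more than 5 kb from a start site.

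The alternatives were other overlap rules, a −log10 q of at least 5, windows of 500 bp and 2.5 kb, each replicate or series list alone, the most upstream start site alone, no joining of peaks or joining within 3 kb, CpG matching and a CpG window of 500 bp. Added after seeing the data were peaks that cover a start site, start sites of protein-coding transcripts only, and genes with no start site of another gene within 1 kb. The overlap code was tested on 1000 simulated peaks with 600 planted partners and found 600, as did bedtools 2.31.1. On simulated lists of genes, the marking test called 5.0% of 200 random lists and 73.5% of 200 lists marked at 90% among 20000 genes; the width test called 5.5% of 200 random lists and 98.0% of 200 lists made 1.8 times wider among 14000 genes. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.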

Results

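Trimethylation of histone H3 at lysine 4 (H3K4me3), a chromatin mark found mainly at the start sites of active and poised genes, was mapped by chromatin immunoprecipitation sequencing in lung from B6NCrl mouse embryos at embryonic day 16.5, the stage at which the branching airways give way to the first alveolar progenitors. There was 1 group with 2 biological replicates, each a pool of lungs from male and female embryos; the labels give 41 embryos for replicate 2 and no number for replicate 1. With a single tissue and stage there was no contrast between groups. The comparisons the design allows are those between the replicates, between the deposited peak lists, and between groups of genes within the tissue. Read numbers are not given in the peak lists, so the sequencing depth is unknown. All coordinates are on mm10.

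Most promoters with a peak had it in both replicates, with 14539 protein-coding genes marked in both, 211 in replicate 1 only and 48 in replicate 2 only, and the peaks without a partner were weak. Replicate 1 had 30235 peaks over 36.6 Mb with a median width of 895 bp, and replicate 2 had 27789 peaks over 32.3 Mb with a median width of 929 bp. Of the peaks of replicate 2, 94.1% (26153; 95% Wilson interval 93.8 to 94.4) were found in replicate 1, and of those of replicate 1, 78.9% (23847; 78.4 to 79.3) were found in replicate 2, where at least 50% of either peak had to overlap. After shifting the peaks along their chromosomes by 1 to 10 Mb, 2.02% ± 0.20 (SD, 100 shifts) of replicate 1 peaks and 2.21% ± 0.22 of replicate 2 peaks met the same rule, with highest values of 2.68% and 3.03%. The 5941 peaks of replicate 1 that no replicate 2 peak touched had a median fold of 3.34 and a median width of 245 bp, against 24.1 and 1286 bp for its shared peaks, and 27.4% (26.2 to 28.5) of them lay within 1 kb of an annotated start site, against 71.7% of the shared ones. The 1265 peaks of replicate 2 with no partner were as weak, with a median fold of 3.50, a median width of 213 bp and 26.2% (23.8 to 28.7) near a start site. The fold is the authors' value for each peak, used here to describe and rank peaks.

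Across the 23847 shared peaks, the log2 fold of the replicates had a Pearson r of 0.949 and a Spearman rho of 0.938; these are across peaks, which are not independent replicates. The relation held at promoters (r = 0.941 over 17088 peaks) and was looser away from them (r = 0.842 over 6759 peaks). Each of these replicate 1 peaks was paired with the replicate 2 peak of largest overlap, so a replicate 2 peak can enter more than once. Over these pairs the median fold was 24.1 in replicate 1 and 19.6 in replicate 2. Counted once each, the 26153 shared peaks of replicate 2 had a median fold of 16.4. The median ratio of replicate 2 to replicate 1 was 0.799, and the log2 ratio had an SD of 0.47 over peaks. Whether the folds of the replicates are ratios to the same kind of reference is not given in the sources used here, so this ratio cannot be read as a difference in the mark. In 130 pairs the fold of replicate 2 was over 4 times that of replicate 1. There, replicate 1 peaks with a median width of 257.5 bp were paired with replicate 2 peaks with a median width of 2241 bp. In 7 pairs the fold of replicate 1 was over 4 times that of replicate 2, with median widths of 2331 and 2090 bp. The pairing started from replicate 1 peaks only, so these counts cannot be read as more peaks being stronger in replicate 2.

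**Figure D1:**
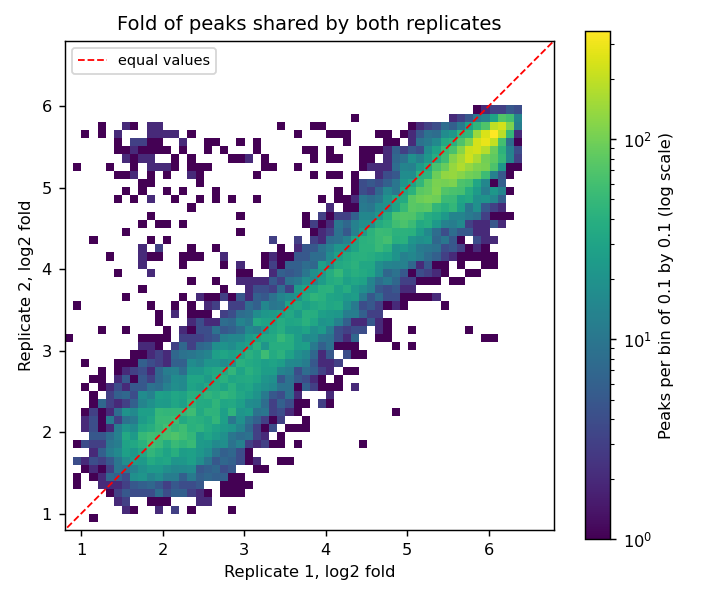
Log2 fold of the 23847 peaks shared by both replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis; the colour gives the number of peaks per bin on a log scale and the dashed line marks equal values. Most peaks lie close to a line somewhat below equality, with a Pearson r of 0.949 and a median ratio of 0.799. Each replicate 1 peak is paired with the replicate 2 peak of largest overlap. The scattered bins at the upper left hold the 130 pairs with an over 4 times higher fold in replicate 2, with median widths of 257.5 and 2241 bp.

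The series also holds a list called on both replicates together (the pooled list, 29346 peaks) and a list made from it and the replicates' lists (the replicated list, 26819 peaks). Each of the 26819 replicated peaks was identical in position and fold to a pooled peak. The 2527 pooled peaks left out of it (8.61%) were weak, with a median fold of 2.99 against 18.1 for those kept. Of the replicated list, 88.2% (23655 peaks, median fold 25.1) were found in both replicates' own lists, 8.39% (2249, median fold 3.48) in replicate 1 only and 1.95% (524, median fold 3.47) in replicate 2 only. A further 391 peaks (1.46%, median fold 3.04, median width 232 bp) were found in neither.

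H3K4me3 in these lungs was a promoter mark by position. Of the peaks on the main chromosomes, 62.4% (61.9 to 63.0) in replicate 1 and 67.6% (67.0 to 68.1) in replicate 2 lay within 1 kb of an annotated transcript start, against 10.2% ± 0.73 and 10.1% ± 0.75 (SD, 100 shifts) for shifted peaks. Promoter peaks held 84.2% and 86.2% of the covered base pairs. Their median fold was 35.0 and 27.6, against 4.26 and 4.82 for the other peaks, of which most had their summit in an intron (5456 of 11350 and 4170 of 9000) or between genes (4652 and 3765). The widest domains more than 5 kb from any start site, with peaks up to 1 kb apart joined, were a 7.33 and 6.99 kb domain (replicates 1 and 2) on chromosome 13 at 21166416 to 21173749, 5.70 kb from the nearest start site, that of Trim27, and a 6.36 and 6.19 kb domain on chromosome 11 at 119052830 to 119059188, 11.9 kb from Cbx8, a subunit of Polycomb repressive complexes. The next lay in gene bodies. They were in Bcor on chromosome X, with 5595 and 5546 bp at 12086702 to 12092296, and in the noncoding gene Lncppara on chromosome 15, with 5451 and 5412 bp at 85669195 to 85674645. Another lay within Fendrr, a noncoding RNA gene next to Foxf1, on chromosome 8 at 121072971 to 121077006, with 4.04 and 3.77 kb. The remaining 5 of the 10 widest lay outside annotated genes, nearest to the annotated start sites of Gm22614, Shf, Olfr1421-ps1, Olfr1368 and Dhx37. They were 3.31 to 4.20 kb wide in the replicate with the smaller width. Start sites of genes that the gene models lack were not considered. None of these 10 domains is therefore shown to lie away from every start site.

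Of 21911 protein-coding genes, 14539 (66.4%; 65.7 to 67.0) had a peak within 1 kb of a start site in both replicates and are called marked below. Another 211 were marked in replicate 1 only, 48 in replicate 2 only and 7113 in neither. Promoter CpG content sorted the genes: with the genes split by CpG ratio into 10 groups of equal size, 6.07% (5.14 to 7.15) were marked in the lowest group, 47.5% in group 4 and 99.4% (98.9 to 99.6) in the highest. Of the 10061 genes with a ratio of at least 0.6, 98.2% were marked, against 39.4% of the other 11850. Gene families that are silent outside their own sensory or skin cells were almost free of the mark, with 2 of 1134 olfactory receptors (Olfr94 and Olfr1033), 1 of 328 vomeronasal receptors (Vmn1r4) and 0 of 57 keratin-associated proteins, which allows a share of up to 6.31% (Wilson); each was below the other genes by Fisher's exact test, with an adjusted exact p of at most 7.81e-27. These 3 marked receptors were named after their values were seen. Vmn1r4 had a start site of another gene within 1 kb, so its peak cannot be given to the receptor. Among the controls at the other end, all 24 housekeeping genes and all 26 cell cycle genes were marked, as were 76 of 79 ribosomal protein genes.

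Genes on the lists for lung cell types and branching signals were marked more often than genes on the lists for other organs. Over lists fixed before the data were examined, 145 of 187 genes of lung cell types and branching signals (77.5%; 71.04 to 82.9) were marked, against 56 of 134 genes of brain, heart, skeletal muscle, liver, gut, kidney and germ line (41.8%; 33.8 to 50.3). The odds ratio was 4.81 (2.88 to 8.05; Fisher's exact test, 2-sided, p = 7.69e-11, over genes, which are not replicates). In the replicates taken alone it was 4.89 and 5.12. The macrophage and leukocyte list was counted among the lung lists. The erythroid list, with 3 of 14 marked, was in neither pool. Among the members with a CpG ratio of at least 0.6 the shares were 98.4% of 64 and 81.1% of 37, a difference of 17.4 percentage points in place of 35.7 (exact p = 0.00345). Of all protein-coding genes at that ratio, 98.2% were marked. In the replicate with the smaller width, the median domain of marked genes was 3344 bp in the lung lists and 1212.5 bp in the others. The lists were not matched for the kind of gene, such as regulators or genes of mature cell function. Neither difference can therefore be given to tissue alone.

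In the epithelium, 26 of 28 distal and alveolar genes were marked (92.9%; odds ratio 6.60, adjusted exact p = 0.00363 by Fisher's exact test over 25 lists). They included Nkx2-1, the transcription factor that specifies lung epithelium, with the widest domain of any protein-coding gene by the smaller of the 2 replicates' widths (20785 bp in replicate 1, where Hoxb3 to Hoxb6 and Nr2f2 were wider, and 20871 bp in replicate 2), and Irx2 (14159 and 14396 bp), Foxa1 (15922 and 13978 bp) and Foxa2 (15284 and 12792 bp), regulators of endoderm. Sftpc, the surfactant protein C gene, which was named after its value was seen, had a domain of 6693 and 5709 bp. The surfactant genes Sftpa1 and Sftpd had no peak in either replicate. The airway list stood lower, at 12 of 24 (adjusted exact p = 0.160), and did not pass the test. Sox2, which marks the proximal airway, had 5259 and 4398 bp, Ccno and Rfx3, both needed for multiciliated cells, 3608 and 3062 bp and 2931 and 2850 bp, and Ascl1, the neuroendocrine factor, 2808 and 2571 bp. Among the secretory genes, Agr2, Bpifa1 and Cyp2f2 were unmarked, and Spdef and Scgb3a2 were marked at folds of 2.66 to 8.99, in domains that did not overlap between the replicates. Among the ciliary genes, Dnah5 was unmarked, and Ccdc39 (1064 and 793 bp) and Foxj1 (2674 and 2383 bp) were marked. Spdef, Scgb3a2, Ccdc39 and Foxj1 were named after their values were seen. The neuroendocrine granule gene Chga had a 377 bp peak of fold 4.89 in replicate 1 only. The distal call was lost when only the most upstream start site of each gene was used (78.6%, adjusted exact p = 0.171), and the airway list fell below the other genes when a peak had to cover a start site (41.7%, adjusted exact p = 0.0474), an alternative chosen after seeing the data.

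**Figure D2:**
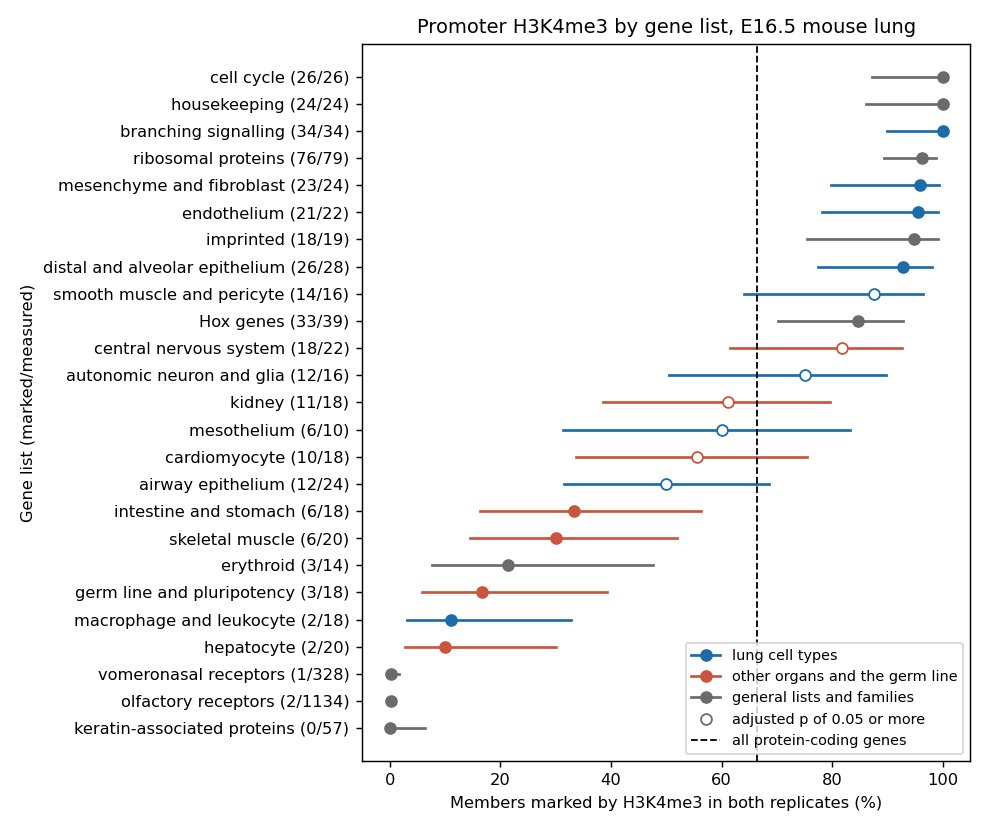
Share of each list's genes marked in both replicates, in percent, with 95% Wilson intervals. Blue lists are lung cell types and branching signals, and red ones other organs and the germ line. Grey ones are general lists, families and the erythroid list, and open circles did not pass the test. The branching, mesenchymal, endothelial and distal epithelial lists lie above the dashed line at 66.4% for all protein-coding genes, and the hepatocyte, leukocyte, germ line and sensory receptor lists lie far below it.

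The mesenchyme, the endothelium and the signals of branching were marked almost throughout. Of 24 mesenchymal genes 23 were marked (95.8%, adjusted exact p = 0.0019). They included the T-box factors Tbx5 (17546 and 16575 bp), Tbx2 (16026 and 16080 bp) and Tbx4 (10770 and 9902 bp) and Foxf1 (12300 and 12114 bp), a target of hedgehog signalling in lung mesenchyme. Lum had only a 215 bp peak of fold 2.56 in replicate 2. Of 22 endothelial genes 21 were marked (95.5%, adjusted exact p = 0.00406). The widest domains were at Egfl7 (10132 and 8504 bp), Sox17 (7097 and 6341 bp), Esam (5844 and 4965 bp) and Aplnr (4784 and 4845 bp). Vwf had a 532 bp peak of fold 3.46 in replicate 1 only. The endothelial call was lost when a peak had to cover a start site (77.3%, adjusted exact p = 0.303). All 34 branching genes were marked (adjusted exact p = 5.25e-06 by Fisher's exact test). Shh had 10503 and 10646 bp, its receptor Ptch1 18125 and 9398 bp, the fibroblast growth factor receptor Fgfr2 8630 and 8281 bp and Wnt5a 7788 and 7789 bp. The smooth muscle and pericyte list had 14 of 16 marked (87.5%, adjusted exact p = 0.144), and Pdgfrb, Kcnj8, Cspg4 and Notch3 had 2653 to 4169 bp. It passed the test within the CpG groups (adjusted exact p = 0.0255) and in replicate 1 alone (93.8%, adjusted exact p = 0.0407). Pln was unmarked and Cnn1 had a 1360 bp domain of fold 3.70 in replicate 1 only. Of the mesothelial genes 6 of 10 were marked (adjusted exact p = 0.741). Podxl, Krt19, Wt1 and Aldh1a2 had 1434 to 5530 bp, and the differentiation markers Msln, Muc16, Upk1b and Upk3b had no peak. Among genes of autonomic neurons and glia 12 of 16 were marked (adjusted exact p = 0.651). Ednrb (5668 and 5549 bp), Erbb3, Hand2 and Foxd3 were widest, Dbh, Phox2b and Plp1 were unmarked, and Sox10 had a peak in replicate 1 only.

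Blood cell genes were mostly without the mark. Of 18 macrophage and leukocyte genes 2 were marked (11.1%; 3.10 to 32.8; odds ratio 0.063, adjusted exact p = 6.82e-06 by Fisher's exact test). They were Runx1 (7465 and 7407 bp), which is also used outside blood cells, and Coro1a (980 and 1276 bp). The complement genes C1qa and C1qb, the macrophage receptor gene Adgre1 and Cd52 had no peak. Csf1r, Ptprc and Spi1 had peaks of 195 to 378 bp in replicate 1 only and Laptm5 one of 205 bp in replicate 2 only, with folds of 2.47 to 4.04. Of 14 erythroid genes 3 were marked (21.4%, adjusted exact p = 0.00171), namely Epor (3069 and 2307 bp), Klf1 and Gypa; at Klf1 and Gypa no peak covered a start site in both replicates. Gata1, Alas2 and Epb42 were unmarked, and so was Hba-a1, whose near-identical copy makes reads hard to place. Within the 10 CpG groups, neither list passed the test (exact conditional test, odds ratio 0.276 and adjusted exact p = 0.264 for leukocytes, 0.787 and adjusted exact p = 1.00 for erythroid genes).

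Among the lists of other organs, 4 passed the test and all 4 were below the other genes. Of 20 hepatocyte genes 2 were marked (adjusted exact p = 1.33e-06), Apoh and Trf, both with a start site of another gene within 1 kb. Alb, Afp, Ahsg and Apoa1 were unmarked, and Proc had a peak of fold 5.84 in replicate 1 only. Germ line and pluripotency genes had 3 of 18 marked (adjusted exact p = 6.52e-05), Utf1, Dazl and Dppa3, each with domains of 651 to 1254 bp, and Ddx4, Dppa4, Figla and Mael without a peak. Skeletal muscle had 6 of 20 (adjusted exact p = 0.00239): Mylpf, Actn3 and Ckm, each with a start site of another gene within 1 kb, Pax7 with 2041 and 1003 bp at folds of 4.89 and 4.45, and Pax3 and Actn2. The contractile and receptor genes Acta1, Cacna1s, Chrna1 and Chrng had no peak. Intestine and stomach had 6 of 18 (adjusted exact p = 0.00763). Gata5 (5412 and 4913 bp), Satb2, Lgr5 and Atoh1 were widest, Alpi, Fabp1, Fabp2 and Gkn1 were unmarked, and Cdx2 and Pdx1 had peaks in replicate 1 only at folds of 3.07 and 4.24. The call was lost in replicate 1 alone (44.4%, adjusted exact p = 0.0602) and in the pooled list (44.4%, adjusted exact p = 0.0594). Within the CpG groups the skeletal muscle call was lost (adjusted exact p = 0.097) and the other 3 held, with an adjusted exact p of at most 0.0255.

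The brain, kidney and heart lists did not pass. Central nervous system genes had 18 of 22 marked (81.8%, adjusted exact p = 0.208), but at a median fold of 9.59 and 6.70. Pax6 (2814 and 2721 bp), Eomes, Foxg1 and Neurog2 were widest. Gfap, Neurod6 and Slc17a6 were unmarked and Otx2 had a 312 bp peak in replicate 1 only. Kidney genes had 11 of 18 (adjusted exact p = 0.651). Hnf1b (6996 and 5269 bp), Eya1, Osr1 and Six2 were marked, the transporter genes Slc12a1, Slc12a3 and Aqp2 and the gene Kap were unmarked, and Nphs1 had a peak in replicate 1 only. Cardiomyocyte genes had 10 of 18 (adjusted exact p = 0.374). Ryr2 and Gata4 were marked, as were Myl3 and Myl4 beside start sites of other genes. Myh6, Myl7, Nppa and Nppb were unmarked, and Hand1 and Myl2 had peaks in replicate 1 only. With peaks of −log10 q of at least 5, the cardiomyocyte list was below the other genes (38.9%, adjusted exact p = 0.0373).

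The median domain of a marked gene was 1887 bp wide in the replicate with the smaller value (quartiles 1381 and 2557 bp), and 31 genes reached 10 kb in both replicates; across genes, the log2 widths of the replicates had an r of 0.945. After Nkx2-1, the widest by the smaller width were Nfib (17165 and 17218 bp), a factor of lung maturation, Tbx5, Nr2f2 (25461 and 16237 bp), Tbx2, the Hoxb3 and Hoxb4 domain (30591 and 15730 bp), Zeb2 (15332 and 15225 bp), the domain over Hoxa3, Hoxa5, Hoxa6 and the overlapping gene Gm28308 (14571 and 14181 bp), Irx2, Meis1 (14145 and 14471 bp) and Foxa1. Of the 18 lists with at least 5 marked genes, 8 were wider than random sets of marked genes (permutation test, 100000 draws, 2-sided, Benjamini-Hochberg adjusted). These were branching signals (median 4327 bp, adjusted permutation p = 0.00012), mesenchyme (4082 bp, 0.00012), distal epithelium (3456 bp, 0.00012), imprinted genes (3217 bp, 0.00036), endothelium (3002 bp, 0.00072), cell cycle (2725 bp, 0.0027), housekeeping (2585 bp, 0.0102) and ribosomal proteins (2310.5 bp, 0.0028). The adjusted permutation p of 0.00012 comes from 2e-05, the smallest p that these permutations can give. The imprinted list (18 of 19 marked, adjusted exact p = 0.00946) was led by Gnas (10352 and 8611 bp), Igf2 (6846 and 6321 bp), Grb10 and Mest, and Ndn was unmarked. The widest cell cycle domains were at Mki67 (4290 and 4368 bp), Aurka, Plk1 and Rrm2, and the widest housekeeping ones at Actb (7572 and 5432 bp), Tubb5, Tbp and Ywhaz. Without joining peaks up to 1 kb apart, the housekeeping and imprinted lists were no longer wider (adjusted permutation p = 0.415 and 0.0585).

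A set of 4 lists was narrower than random sets, namely cardiomyocyte (989 bp, adjusted permutation p = 0.0028), skeletal muscle (1071 bp, 0.0297), central nervous system (1202 bp, 0.0028) and Hox genes (1439 bp, 0.0103), all by the permutation test. In replicate 1 alone only the cardiomyocyte list of these stayed narrower (955.5 bp, adjusted permutation p = 0.000434); the central nervous system list then had a median of 2113 bp (adjusted permutation p = 0.928), skeletal muscle 1801.5 bp (0.603) and the Hox genes 1781 bp (0.150). Against random sets matched on the CpG groups, the nervous system (adjusted permutation p = 0.00895) and Hox lists (0.0296) stayed narrower and the other 2 did not (0.0549 and 0.101). Neighbouring Hox genes can share a domain, which the test counts once for each gene. The upper quartile of the Hox list was 13286 bp, so its low median does not describe all of its genes. With peaks up to 3 kb apart joined, or with peaks of −log10 q of at least 5, 1 list in place of 4 was narrower. The airway, smooth muscle, mesothelium, autonomic, intestine and kidney lists did not pass the test of width, with adjusted permutation p of 0.178 to 0.945.

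**Figure D3:**
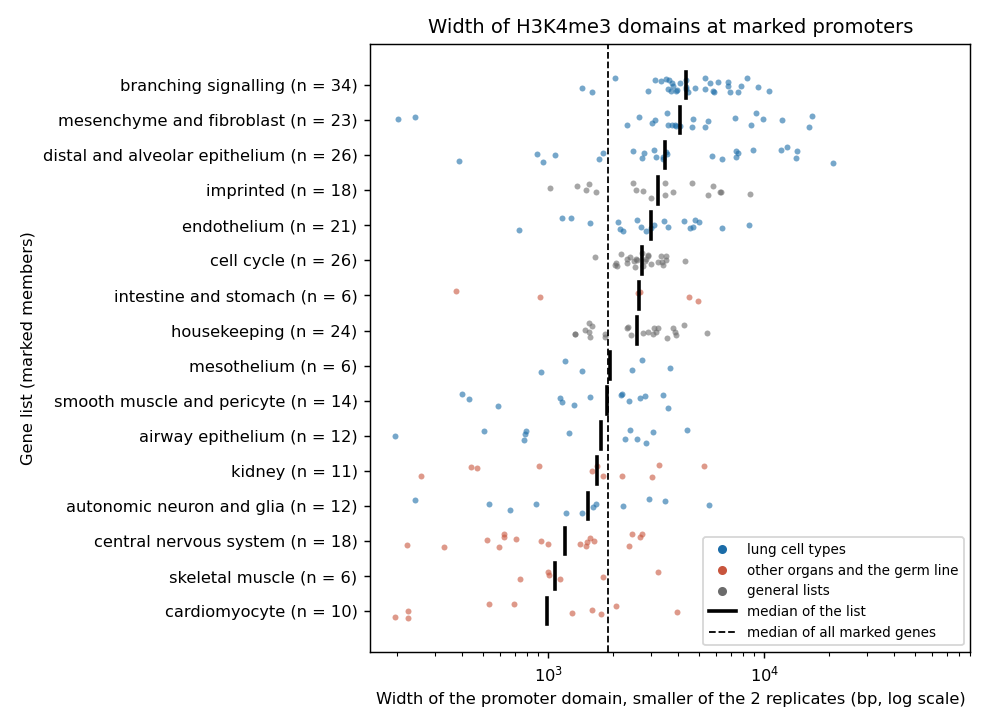
Width of the H3K4me3 domain at each marked gene, in bp on a log scale and as the smaller value of the 2 replicates, for the fixed lists with at least 5 marked genes; each point is a gene, black bars are list medians, and the dashed line is the median of all marked genes, 1887 bp. The branching, mesenchymal and distal epithelial lists have medians of 4327, 4082 and 3456 bp, and the cardiomyocyte list has a median of 989 bp.

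The Hox genes, which set position along the body axis, split by cluster. Of 39 genes 33 were marked (84.6%, adjusted exact p = 0.023), a call lost within the CpG groups (odds ratio 0.670, adjusted exact p = 0.322), with peaks of −log10 q of at least 5 (66.7%, adjusted exact p = 0.868) and under 4 other settings given below. In the Hoxa cluster on chromosome 6 the genes of paralog groups 1 to 6 had a median domain of 13733.5 bp. Hoxa1 and Hoxa2 shared one of 14213 and 13286 bp, Hoxa3, Hoxa5 and Hoxa6 shared another, and Hoxa5 had a fold of 59.3 and 43.1. Hoxa4 had 3385 and 2713 bp and Hoxa7 2548 and 2223 bp. Beyond them Hoxa9 (1990 and 598 bp) had folds of 4.89 and 4.63. The widest domain of Hoxa10 was 808 bp at 52233542 to 52234349 in replicate 1 and 214 bp at 52240309 to 52240522 in replicate 2. The folds were 4.52 and 4.18. Each of these places also had a peak of the other replicate. These had folds of up to 4.36 in replicate 1 and of 3.93 in replicate 2. Hoxa11 was marked in replicate 1 only, and Hoxa13 had 2234 and 1439 bp. In the Hoxb cluster on chromosome 11, Hoxb3 to Hoxb6 had start sites at a domain of 30591 bp in replicate 1. This domain was split in replicate 2 into 15730 bp at Hoxb3 and Hoxb4 and 13790 bp at Hoxb5 and Hoxb6. Hoxb3 also held a separate run of peaks, narrower than its widest domain. It reached from 96331714 to 96346460 in replicate 1 and from 96331749 to 96346375 in replicate 2. Hoxb2 had 3940 and 3735 bp, Hoxb7 and Hoxb8 5190 and 5075 bp, Hoxb9 1807 and 1618 bp, Hoxb1 1290 and 1193 bp and Hoxb13 909 and 490 bp. The Hoxc and Hoxd clusters on chromosomes 15 and 2 had no domain above 1914 bp. There, Hoxc4 (1914 and 1619 bp), Hoxc5 and Hoxc6 had folds of 5.86 to 21.8, and Hoxd1, Hoxd8 and Hoxd13 had folds of 13.02 to 23.1. Hoxc9, Hoxc10 and Hoxc13 were at folds of 1.97 to 3.12, Hoxd3, Hoxd4, Hoxd9 and Hoxd11 at 4.67 to 8.81. Hoxc8 and Hoxd10 were marked in replicate 1 only, and Hoxc11, Hoxc12 and Hoxd12 in neither. The contrast between clusters was not tested, since neighbouring genes share domains. Tests of the whole Hox list count such a domain once for each gene, which limits their p-values.

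**Figure D4:**
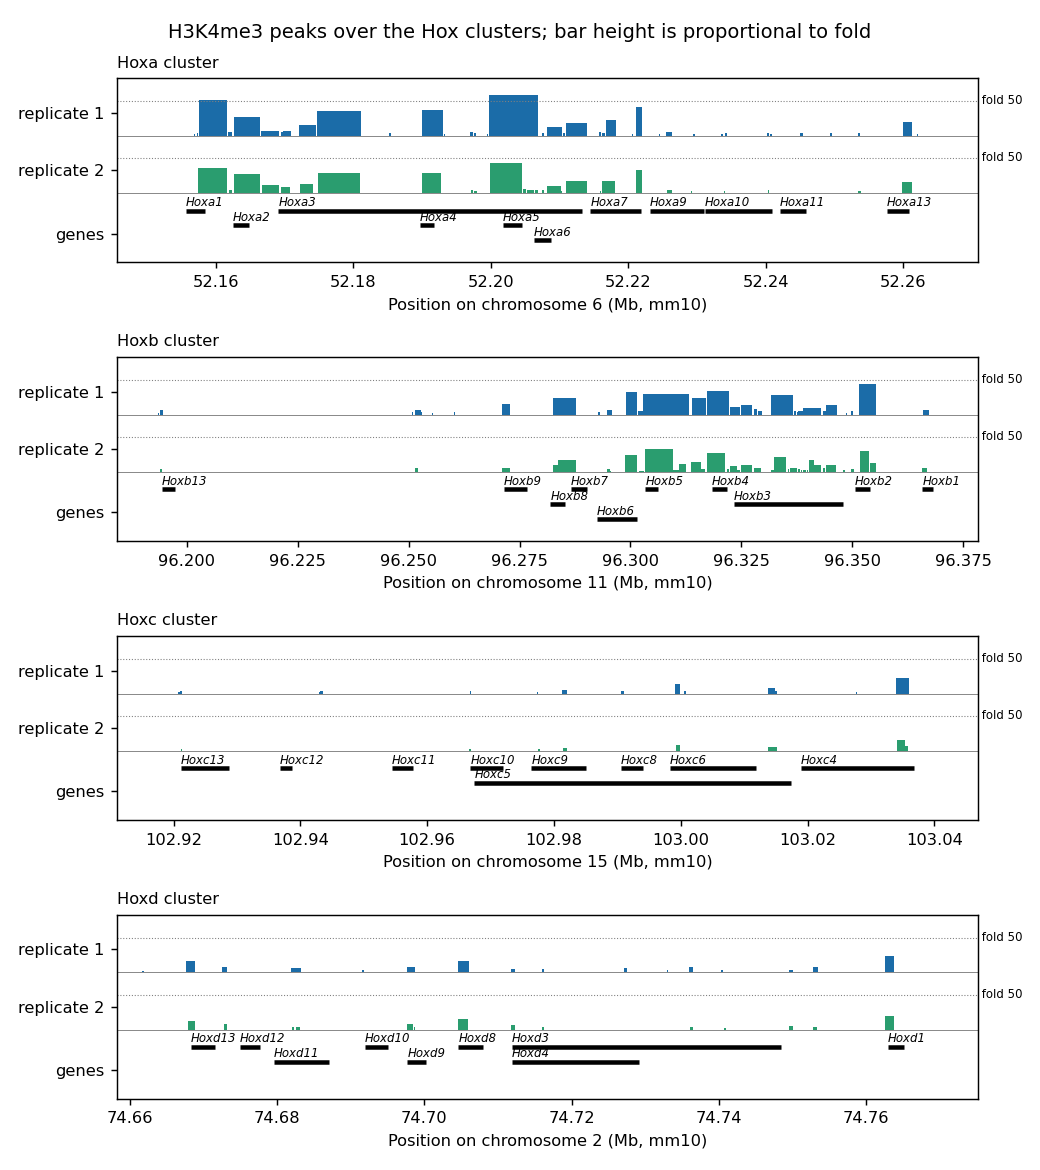
Peaks of both replicates over the Hox clusters, with position in Mb on mm10 on the horizontal axis, each peak drawn to scale with its height proportional to fold (dotted lines at a fold of 50) and genes below. Counting only the widest domain of each gene, the widest lie over Hoxa1 and Hoxa2, over Hoxa3, Hoxa5 and Hoxa6, and over Hoxb3 to Hoxb6. No domain of a Hoxc or Hoxd gene is wider than 1914 bp.

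Genes marked in a single replicate were mostly at the edge of detection or of the window. The 211 of replicate 1 had a median fold of 3.65 and the 48 of replicate 2 a median fold of 3.72. The highest were Gckr, Lor, Tmem88b, Lmntd2 and Adam8 in replicate 1, with folds of 31.9 to 54.0, but replicate 2 had its nearest peak 1022 to 1115 bp from their start sites, just outside the window of 1 kb. In replicate 2 they were Clec11a (fold 43.9), Igfn1 (20.3) and 1700086D15Rik (7.42), where the nearest peak of replicate 1 lay 1003 to 1009 bp away, and Cyth4 (5.01) and Dpep1 (4.98), where it lay 14.9 and 17.8 kb away.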

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

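Of the tests in this part, those on CpG content, on cells too few in number and on broken domains were chosen after the results were seen. The comparisons behind those on CpG content and on broken domains were fixed in advance, but their values had been seen when they were set against an explanation. Peaks on sequences that are not placed on a chromosome were outside the comparisons and are listed as a signal in data not used there. Replicate 1 had 11 such peaks and replicate 2 had 10; 10 of the 11 were shared, on 5 unplaced or unlocalised sequences, with median folds of 9.73 and 9.07, and no test was made.

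Macrophage and leukocyte genes were rarely marked, at 2 of 18. Blood cells too few for a peak in each replicate and low CpG content of these promoters cannot be told apart. On the former, 4 of the 18 genes (22.2%) were marked in exactly 1 replicate, against 1.18% of all protein-coding genes (odds ratio 11.8 within the CpG groups, exact p = 0.000756), but these genes had been seen before the test was chosen, so it does not support the explanation; the erythroid list, marked at 3 of 14, had 0 such genes, and the cardiomyocyte list and the intestine and stomach list had 2 of 18 each. On the latter, the odds ratio for marking within the CpG groups was 0.276 (exact p = 0.164), and the list is small. No biological explanation was tested, as the design holds 1 tissue and stage.

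Central nervous system genes, of which 18 of 22 were marked, had narrow domains, with a median of 1202 bp. For the smaller of the 2 widths, the tables argue against CpG content at the most upstream start site as the whole cause. Sets matched on the CpG groups had a median of 1755.5 bp (permutation p = 0.00398). This value had been seen before the test was chosen, and the list was not narrow in replicate 1 alone. Domains broken into separate peaks in replicate 2 stay open: the median was 2113 bp in replicate 1 alone, against 2080 bp for random sets, and 1895 bp with peaks within 3 kb joined (adjusted permutation p = 0.814), but these values had been seen before the test was chosen. Weak enrichment stays open as well: the median fold was 8.01 against 41.7 for all marked genes, and sets matched on fold had a median of 766 bp, where the prediction was no difference and the list was wider (permutation p = 0.0189). No biological explanation was tested.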

How the results depend on the processing

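The alternatives chosen after the results were seen were peaks that cover a start site, start sites of protein-coding transcripts only, and genes with no start site of another gene within 1 kb. The difference between the lung lists and those of other organs kept its direction and its side of the threshold under all 12 of its alternatives, with 17.4 to 37.2 percentage points. Genes marked ran from 13711 to 14773, lists more often marked from 6 to 10, lists less often marked from 6 to 10 and lists with wider domains from 7 to 9. Of the single lists' shares and widths, 351 values under an alternative kept direction and side, 28 lost the call, 9 gained one and 19 reversed. The depth is unknown, so its limit on weak peaks could not be measured; the cause of the changes below was not tested, except where a stricter or wider rule by its construction keeps fewer or more peaks.

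The share of replicate 1 peaks found in replicate 2 was 80.4% with any overlap, 72.8% with 50% of both peaks, 86.5% with a −log10 q of at least 5, 89.3% among peaks at or above the median fold and 86.7% with peaks joined first. For replicate 2 peaks in replicate 1 these were 95.4%, 79.2%, 98.6%, 99.5% and 96.0%. Pooled peaks in replicate 1 were at 93.2%, 88.9%, 95.2% and 99.3% under the first 4 of these rules. With 50% of both peaks, the −log10 q limit and the median fold, pooled peaks in replicate 2 were at 78.7%, 86.3% and 91.8%, replicated peaks in replicate 1 at 93.0%, 95.4% and 99.9%, and in replicate 2 at 85.02%, 86.6% and 97.8%. The correlation of the replicates was 0.958 for −log10 p and 0.941 for promoter peaks.

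With windows of 500 bp and 2.5 kb and with the −log10 q limit, the promoter share was 58.0%, 72.5% and 73.8% in replicate 1, 63.1%, 77.0% and 78.5% in replicate 2, 59.2%, 72.7% and 73.1% in the pooled list and 63.2%, 74.8% and 73.3% in the replicated list. For peaks found in 1 replicate only it was 17.2%, 50.7% and 34.1% in replicate 1 and 17.2%, 47.0% and 31.0% in replicate 2. With the −log10 q limit there were 3027 such peaks in replicate 1 (median fold 4.96) and 290 in replicate 2 (5.39). With a CpG window of 500 bp, 8.30% of the lowest CpG group was marked.

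Within the CpG groups the odds ratio changed side for mesothelium (60% marked), cardiomyocyte (55.6%), kidney (61.1%) and Hox genes (84.6%). For the autonomic list the odds ratio changed side at 62.5% with the 500 bp window and with the most upstream start site. It also did so at 56.25% with the −log10 q limit and with peaks that cover a start site. Such a change of side is counted whatever the p and is not a call. The Hox call was also lost with the 500 bp window, the most upstream start site, peaks that cover a start site and protein-coding transcripts only. Narrower lists, 4 in the report, were 1 with peaks joined within 3 kb, 1 with the −log10 q limit, 2 with CpG matching and 2 to 4 with a replicate left out. Median widths moved to the other side of random sets for smooth muscle (2117 to 2653 bp with a replicate left out, 1869 bp with CpG matching), the airway (1983 bp) and Hox genes (2254 bp) with the −log10 q limit, and mesothelium (1420.5 bp unjoined, 1941 bp joined within 3 kb and with CpG matching, 1729 bp with the −log10 q limit). Over the replicates left out in turn, the widths were 1248 to 2113 bp for the central nervous system and 1841 to 2629 bp for intestine and stomach, each reversed without replicate 2.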

Other observations

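The noncoding and sex-linked genes in this part were chosen after the main results were seen; the bounds of the tests in this part were set before their results were. Of the long noncoding RNA genes, 868 of 5839 intergenic (14.9%, interval 14.0 to 15.8) and 1041 of 2956 antisense genes (35.2%, interval 33.5 to 37.0) were marked in both replicates. They were not tested against protein-coding genes. Genes with a start site of another gene within 1 kb were not left out, so a peak counted here can belong to that other gene. The imprinted noncoding genes H19 (3228 and 2862 bp), Meg3 (2930 and 2577 bp), Kcnq1ot1 (3101 and 2538 bp) and Airn (2756 and 2657 bp) all had domains, with folds between 14.4 and 39.2. Malat1 (8047 and 7739 bp), Neat1 (5015 and 5865 bp) and Mir17hg, the host of the miR-17 cluster (4098 and 3059 bp), were wide, and Fendrr shared the 12300 and 12114 bp domain of Foxf1. Hotair, in the Hoxc cluster, had no peak. On the Y chromosome, Ddx3y, Eif2s3y, Kdm5d and Uty were marked in both replicates at folds of 21.2 to 22.2 and 12.2 to 14.6, and Zfy1 and Sry were not, in pools that the labels describe as male and female. Xist, the RNA that coats the inactive X chromosome, was marked at folds of 20.7 and 22.1 over 3573 and 3593 bp.

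X-linked promoters carried a lower fold than autosomal ones. Among marked genes with a CpG ratio of at least 0.6, the median log2 fold (mean of the replicates) was 4.94 for 238 X-linked genes, against 5.53 for 9633 autosomal genes, and the medians of the 19 autosomes ran from 5.48 (chromosome 7) to 5.61 (chromosome 16). The tables argue against CpG content at the most upstream start site as the cause, since the difference from sets matched on the CpG groups was -0.52 (permutation p = 0.0002, the smallest that 10000 draws can give). A candidate explanation is that a single X chromosome is active in each cell: the difference was -0.52 in replicate 1 and -0.51 in replicate 2, a ratio of 0.699 and 0.703. This is the difference to be explained, seen in each replicate, so it does not tell this explanation from other causes of a lower fold. Fewer copies of the X in a pool of both sexes, with no inactivation, would lower genes that escape inactivation as well, but Ddx3x, Eif2s3x, Kdm5c, Kdm6a, Pbdc1 and Utp14a lay 0.72 above the other X-linked genes in median log2 fold (permutation p = 2e-05, the smallest possible), at 5.66 against 5.53 for autosomal genes. These 6 genes could be high for another reason, and the sex ratio of the pools is not given.

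The 15 widest genes, among them Foxa1, Tbx2, Tbx5, Irx2 and Meis1, prompted the hypothesis that families of developmental regulators have wide domains in general. The families chosen were Fox, Sox, Tbx, Irx, Gata, Klf, Meis, Pbx, Id, Smad, sine oculis homeobox and Pax. Of these, only Fox, Tbx, Irx and Meis have a member among the 15. The families of Nkx2-1, Nfib, Nr2f2 and Zeb2 were not tested, so the result covers the chosen families only. Without those 15 genes and all members of the fixed lists, 93 marked members had a median of 2898 bp, against 2002 bp for sets matched on the CpG groups (permutation p = 0.0002, the smallest that 10000 draws can give). The CpG ratio came from the most upstream start site, the width from any start site. The number of start sites per gene was not matched. The 321 marked genes named Zfp, mostly zinc finger proteins, had a median of 1622 bp, below the 1759 bp of their matched sets (permutation p = 0.0064); the difference between these sets was not tested. The Hox genes, some of which are among the 15 widest, were not among the families tested here. Their median domain was narrower than that of CpG-matched sets in the report. This call was not kept against random sets in replicate 1 alone (1781 bp). With peaks of −log10 q of at least 5, the Hox median lay above that of random sets. With all members counted, the widest genes and those of the fixed lists included, medians by family ran from 8335 bp for Meis and Pbx (7 of 7 marked) and 6697 bp for Irx (6 of 6) to 2143 bp for Tbx (11 of 13) and 1204.5 bp for Pax (8 of 9). Named after their values were seen, the widest members were Tbx5, Irx2, Meis1, Foxa1, Smad7 (12688 bp), Gata6 (11921 bp), Id2 (8850 bp), Sox9 (6383 bp) and Klf4 (4769 bp).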
